A study of Homo sapiens with 6 samples.

How the data were processed

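RNA of 95D cells was measured by sequencing of total RNA after removal of ribosomal RNA, with paired reads of 150 bases, per the labels' protocols. The labels describe 6 libraries, 2 each of control medium, glucose deprivation and glutamine deprivation, and nothing says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Alignment and assembly used HISAT2 2.0.5 and StringTie on hg38, per the submitters' processing notes; the annotation, the StringTie version and the strand setting were not given in the sources used here.

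The deposited values were taken to be FPKM, fragment counts that the authors divided by transcript length and by the mapped fragments, for 59609 gene names. No header names this unit. It was inferred from fractional values, from sums of 493130 to 571210 per library, and from low values of single-exon genes, which fall on steps of whole reads. A combined deposited table, named as raw, held identical values in the 5 columns used here and was not used. In 1 value column of the glutamine table the header names glucose deprivation replicate 2. Its sample could not be told from its name, so that column was not mapped or used, and 5 of 6 labelled libraries entered. Depth was inferred from the steps of 3886 to 4275 single-exon genes of 1 to 20 reads per library, of which 95.1% to 95.7% came out whole within 0.05 reads.

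The tests planned before the data were examined were for counts. As the values are FPKM, limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) took their place, and the planned minimum of 3 on the average log2 level of named genes was applied to mean log2(FPKM + 1). The planned TMM scaling was computed on FPKM as an unweighted mean of log ratios to the mean library, trimmed by 30% of ratios and 5% of abundances at each end, over genes with a mean of at least 1 FPKM. Its factors were 0.960 and 0.971 for the controls, 1.01 and 0.979 for glucose deprivation and 1.08 for glutamine deprivation, and all levels printed are FPKM divided by them. For part of the work the values as deposited, without this scaling, were the main values. The return to the planned scaling was made after both had been run on the data.

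Genes with at least 1 FPKM in at least 1 library were tested, 16598 in all. All 5 libraries entered a fit with a coefficient per group, which left 2 residual degrees of freedom, so the lone glutamine-deprived library is assumed to vary like the other groups. Variances were moderated over a trend on the inferred reads of a gene, its mean FPKM times its exon length in GENCODE release 29 (the median length where none was found), without limma's robust option. Adjusted p-values are Benjamini-Hochberg values from limma over the genes tested, two-sided, with a threshold of 0.05. The median SE of a log2 fold change was 0.07 in glucose deprivation and 0.08 in both comparisons with glutamine deprivation.

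The variance trend and the robust option were chosen after several settings of trend, robustness, filter and gene length had been run on both simulated and real data, so this choice was not made blind to its effect. For each comparison 1 set of libraries was simulated from the real gene means and inferred depths, with a dispersion of 0.005 for every gene and 200 genes changed. The share of false calls depends on these settings. As far more genes were called on the real data, it does not estimate the share of false calls there. With the setting used, 8.12% of calls were false in glucose deprivation, 17.5% in glutamine deprivation and 8.38% in the direct comparison, all above the nominal 5%, and 181, 170 and 164 of the 200 genes were recovered. A trend over the FPKM level without the robust option gave 14.3%, 10.5% and 16.2% false calls, with 138, 111 and 109 genes recovered. For glutamine deprivation the setting used is therefore not the one with the fewest false calls. The robust option gave 9.14%, 18.2% and 9.68% over inferred reads and 18.8%, 14.6% and 21.2% over FPKM. On the real data the trend over FPKM without the robust option called 8060, 7395 and 6012 genes, against 9090, 8476 and 7375 here. Of genes changed 1.5-fold, 2-fold and 4-fold, 77.6%, 94.0% and 100% were recovered in glucose deprivation (15636 simulated genes tested), 73.1%, 86.6% and 95.5% in glutamine deprivation (15642) and 58.2%, 89.6% and 98.5% in the direct comparison (15611).

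The 32 gene lists were fixed before the data were examined. Those with at least 5 measured genes, 31 lists, were tested with camera at a preset correlation of 0.01, two-sided. Adjustment was Benjamini-Hochberg over the lists of a comparison. No call held with an estimated correlation, and those p-values stand beside each call. That version rests on 2 residual degrees of freedom and has little power. In glucose deprivation it gave an adjusted p of 0.42 for the mitosis list, with all 34 members lower. Its lack of calls therefore cannot decide whether the calls hold. Genes were named by a rule fixed at the same time. It takes the 8 largest rises and 8 largest falls per comparison with control, 5 and 5 in the direct one, among protein-coding genes past the threshold whose libraries separate the groups and whose mean log2 level is at least 3. It adds up to 4 members of each list, 14 genes fixed for their link to these nutrients, and the 5 genes of opposite direction with the largest direct difference. Some genes that the rule takes are not reported here. Other settings fixed before the data were examined were RLE and upper-quartile scaling, the values as deposited, other filters and thresholds, fits of 2 groups, a replicate block, removal of the 50 most abundant genes, coding genes alone and leaving out each library. Scaling to the total, a pseudocount of 0.1, a robust variance trend over FPKM and removal of a GC and length trend were chosen after seeing the data. In scaling to the total the divisor depends strongly on few genes, as the 5 most abundant held 46.3% to 52.1% of the FPKM sum of each library.

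Gene names were matched to GENCODE release 29 (54960 names) and RefSeq (37629); 3032 names matched neither. Positions are from RefSeq on GRCh38 and are not given for mitochondrial genes. Reads of near-identical copies (histones, HSPA1A and HSPA1B, mitochondrial sequence in the nuclear genome), of overlapping genes and of antisense pairs cannot be told apart in these values. The correlation and covariance of fold changes were set against 100 simulations of unchanged groups. Tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.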

Results

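The series measured RNA levels in 95D cells, a human lung cancer cell line, grown for 48 h without glucose or without glutamine, the main sugar and the most abundant amino acid of the culture medium. Cells were first seeded for 24 h in complete medium, and all media held 10% serum. The serum of both deprived media was dialyzed, and the labels name no dialyzed serum for the control, so a difference in serum between control and both deprivations is not excluded, and the comparison of the deprivations with each other has dialyzed serum on both sides. The comparisons rest on 5 libraries: 2 control libraries, 2 of glucose deprivation and 1 of glutamine deprivation. Inferred depth was 35510000 and 48950000 reads for the controls, 36840000 and 35050000 reads for glucose deprivation and 34600000 reads for glutamine deprivation. At these depths a gene of 2 kb at 1 FPKM rests on 69.2 to 97.9 reads, a counting error of 10.1% to 12.02%. Across the 16598 genes tested, log2 levels of the control replicates correlated with r = 0.991 and those of the glucose deprivation replicates with r = 0.985, and libraries of different groups with r between 0.954 and 0.961; genes are not independent replicates. Below, levels are FPKM after scaling, as mean ± SD (n = 2) for control and glucose deprivation and as the value of the lone library for glutamine deprivation, and fold changes are on the log2(FPKM + 1) scale, ± SE, which understates changes of genes of low abundance.

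The first comparison asked which transcripts changed when glucose was removed. DDIT3, which encodes the stress transcription factor CHOP, rose from 5.25 ± 0.0698 to 33.8 ± 0.363 FPKM, a log2 fold change of 2.48 ± 0.05 (adjusted p = 3.24e-07). The asparagine synthetase gene ASNS rose from 22.3 ± 1.49 to 70.2 ± 0.442 FPKM (1.62 ± 0.05 log2, adjusted p = 2.15e-06), and the endoplasmic reticulum (ER) disulfide isomerase gene PDIA4 from 83.3 ± 0.798 to 228 ± 0.353 FPKM (1.44 ± 0.04 log2, adjusted p = 1.39e-06). The linker histone gene H1-3 fell from 242 ± 17.7 to 19.9 ± 0.529 FPKM (-3.54 ± 0.06 log2, adjusted p = 9.32e-08). TXNIP, whose transcription follows glucose through the factors MondoA and ChREBP, fell from 6.21 ± 0.129 to 1.27 ± 0.133 FPKM (-1.67 ± 0.06 log2, adjusted p = 3.7e-06).

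The other genes that led the increases were JUN (1.95 ± 0.04 log2) and JUND (1.48 ± 0.08), subunits of the AP-1 transcription factor, the mitochondrial phosphoenolpyruvate carboxykinase gene PCK2 (1.36 ± 0.10), the stress transcription factor gene ATF3 (1.35 ± 0.07) and PPP1R15A (1.34 ± 0.04), which directs dephosphorylation of the initiation factor eIF2. Their adjusted p-values lay between 3.24e-07 for JUN and 2.96e-05 for PCK2, and both deprived libraries lay above both controls. All of the 8 genes that led the decreases were histone genes. H2AC4 fell from 407 ± 15.5 to 39.8 ± 5.20 FPKM, H3C1 from 701 ± 6.45 to 81.0 ± 6.02 FPKM and H4C2 from 1026 ± 102 to 181 ± 22.1 FPKM. H2BC8 (-3.24 ± 0.10 log2), H2AC8 (-2.46 ± 0.07), H2AC12 (-2.33 ± 0.07) and H3C13 (-2.25 ± 0.14) also fell. Histone genes have near-identical copies among which reads can be split, so the level of any one of them is uncertain. On GRCh38, DDIT3 lies on chromosome 12 from 57516588 to 57520517, ASNS on chromosome 7 from 97851677 to 97928441, PDIA4 on chromosome 7 from 149003051 to 149028505, JUN on chromosome 1 from 58780791 to 58784047, TXNIP on chromosome 1 from 145992435 to 145996579 and H1-3 on chromosome 6 from 26234212 to 26234987.

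In total 9090 of 16598 genes changed at an adjusted p under 0.05 (limma), 4397 higher and 4693 lower, of which 252 and 174 changed at least 2-fold. Leaving out control replicate 1 gave 5689 genes, leaving out control replicate 2 gave 5862 and scaling to the total gave 5419. The split depended on the scaling, with 59.8% of calls higher under upper-quartile scaling and 67.6% under scaling to the total, against 48.4% here. The 4406 genes with a mean of at least 10 FPKM had a median log2 fold change of -0.16 and the less abundant genes 0.09. The list tests below compared each list with all genes, not with genes of like abundance. In libraries simulated for this comparison 8.12% of calls were false, which does not estimate the share among the real calls.

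Genes of the ER chaperone and unfolded protein response list rose, 21 of 26 measured members higher and 1 lower, the same numbers adjusted over the list alone, with a median log2 fold change of 0.49 (camera adjusted p = 1.99e-08, adjusted p = 0.42 with an estimated correlation). The ER chaperone gene HSPA5, which encodes BiP, went from 79.0 ± 1.98 to 167 ± 13.8 FPKM, HSP90B1 from 174 ± 2.71 to 362 ± 18.3 FPKM and HERPUD1, a component of ER-associated degradation, from 9.71 ± 0.373 to 20.6 ± 0.0239 FPKM. In the ATF4 and CHOP stress response list 19 of 24 members rose and 1 fell (20 and 1 adjusted over the list alone), with a median of 0.82 (camera adjusted p = 9.17e-08, adjusted p = 0.42 with an estimated correlation). Amino acid transporter genes rose as a list, 13 of 21 members higher and 4 lower, also when adjusted over the list alone. Their median was 0.25 (camera adjusted p = 0.0024, or adjusted p = 0.42 with an estimated correlation). SLC3A2, the heavy chain of several transporters, rose from 40.7 ± 1.82 to 95.7 ± 6.31 FPKM, the cationic amino acid transporter gene SLC7A1 from 15.0 ± 0.286 to 32.0 ± 0.511 FPKM and SLC43A1 by 1.26 ± 0.06 log2, whereas the glutamate transporter gene SLC1A3 fell (-0.76 ± 0.07). Cytosolic ribosomal protein genes rose by less, with 50 of 78 higher and 1 lower (51 and 1 adjusted over the list alone), a median of 0.21 (camera adjusted p = 1.41e-07, adjusted p = 0.611 with an estimated correlation) and RPS12 among them (0.45 ± 0.05 log2). That median was 0.32 under scaling to the total.

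Cell division genes fell. All 34 measured mitosis genes were lower, also when adjusted over the list alone. The median was -0.69 (camera adjusted p = 8.93e-15, or adjusted p = 0.42 with an estimated correlation). Members included the mitotic kinase gene AURKA (-1.37 ± 0.04 log2), the kinesin gene KIF20A (-1.34 ± 0.04) and the cyclin B1 gene CCNB1, which went from 90.2 ± 3.20 to 40.0 ± 2.03 FPKM. All 21 measured replication-dependent histone genes fell, also when adjusted over the list alone. The median was -1.38 (camera adjusted p = 4.91e-11, or adjusted p = 0.42 with an estimated correlation). In the DNA replication and S phase list 25 of 38 members fell and 6 rose, with the same numbers adjusted over the list alone. The median was -0.21 (camera adjusted p = 0.000817, or adjusted p = 0.42 with an estimated correlation). The flap endonuclease gene FEN1 (-0.77 ± 0.05 log2) fell, whereas the replication licensing gene CDT1 (1.001 ± 0.06) and the DNA ligase gene LIG1 (0.71 ± 0.04) rose.

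Of 40 nuclear-encoded respiratory chain genes 36 were lower and 0 higher (37 lower adjusted over the list alone). Their median was -0.37 (camera adjusted p = 4.26e-10, or adjusted p = 0.42 with an estimated correlation). The cytochrome c gene CYCS stood at 91.7 ± 1.84 FPKM in control and 42.7 ± 2.23 FPKM without glucose. Of 25 TCA cycle genes 18 fell and 2 rose, also when adjusted over the list alone. Their median was -0.28 (camera adjusted p = 0.000513, or adjusted p = 0.42 with an estimated correlation). The cytosolic isocitrate dehydrogenase gene IDH1 was among those that fell (-1.37 ± 0.05 log2). In the glycolysis and glucose uptake list 13 of 22 members fell and 3 rose, also when adjusted over the list alone. The median was -0.26 (camera adjusted p = 0.00219, or adjusted p = 0.56 with an estimated correlation). The glycolytic enzyme gene PGAM1 went from 166 ± 1.70 to 73.7 ± 2.81 FPKM and the lactate dehydrogenase gene LDHA from 157 ± 0.501 to 91.1 ± 4.79 FPKM, while the hexokinase gene HK2 rose by 0.57 ± 0.06 log2 and the glucose transporter gene SLC2A1 by 0.27 ± 0.08 log2 (adjusted p = 0.0249). Under scaling to the total the medians were -0.17 for the TCA cycle, -0.15 for glycolysis and -0.10 for the S phase list, as the median of all genes moved from 0.02 to 0.11.

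Heat shock protein genes fell as a list (14 of 17 lower and 2 higher, also when adjusted over the list alone). The median was -0.66 (camera adjusted p = 1.71e-05, or adjusted p = 0.42 with an estimated correlation). HSPA1B (-1.59 ± 0.08 log2), whose reads are shared with its near-identical copy HSPA1A, and the mitochondrial chaperonin gene HSPE1 (-1.07 ± 0.05) were among those that fell. Ribosome biogenesis genes fell in 20 of 28 cases with 1 higher, also when adjusted over the list alone. The median was -0.25 (camera adjusted p = 2.8e-05, or adjusted p = 0.42 with an estimated correlation). It was -0.14 under scaling to the total. NOP16 changed by -0.96 ± 0.04 log2. In the NRF2 antioxidant list 13 of 18 members fell and 3 rose, also when adjusted over the list alone. Their median was -0.36 (camera adjusted p = 0.0024, or adjusted p = 0.42 with an estimated correlation). The peroxiredoxin gene PRDX1 (-1.02 ± 0.04 log2) fell and the ferritin light chain gene FTL (0.70 ± 0.05) rose. Interferon-stimulated genes (13 of 20 lower, 2 higher, also when adjusted over the list alone, camera adjusted p = 0.00539, adjusted p = 0.42 with an estimated correlation) fell too, IFITM1 among them (-0.996 ± 0.09 log2). Cholesterol synthesis genes (16 of 24 lower, 5 higher, 16 and 6 adjusted over the list alone, camera adjusted p = 0.0357, adjusted p = 0.42 with an estimated correlation) lost their call without glucose deprivation replicate 1 (adjusted p = 0.0558), under scaling to the total (median -0.10, adjusted p = 0.129) and after removal of a GC and length trend (adjusted p = 0.161). The p53 target list (15 of 20 lower, 5 higher, also when adjusted over the list alone, camera adjusted p = 0.045, adjusted p = 0.511 with an estimated correlation) lost its call in the same settings, with adjusted p = 0.0762 under scaling to the total and 0.0798 after removal of the trend. Leaving out control replicate 1, glucose deprivation replicate 1, glucose deprivation replicate 2 or glutamine deprivation replicate 1 also ended it, with adjusted p-values of 0.0579, 0.0576, 0.0612 and 0.057. Over the alternatives tested with camera at the preset correlation, the adjusted p lay between 0.0192 and 0.0798 for p53 targets and between 0.0267 and 0.161 for cholesterol synthesis. The p53 targets CCNG1 (0.54 ± 0.04 log2) and GADD45A (1.18 ± 0.07) rose.

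Of the genes named in advance for their link to these nutrients, the stress response genes TRIB3 (0.997 ± 0.06 log2) and CHAC1 (0.79 ± 0.17, from 0.926 ± 0.512 to 2.27 ± 0.259 FPKM) rose without glucose. The cystine transporter gene SLC7A11 (0.48 ± 0.04) and the glutamine transporter gene SLC1A5 (0.19 ± 0.05) rose, and ARRDC4, a glucose-responsive relative of TXNIP, fell (-0.96 ± 0.06). The glutamine synthetase gene GLUL fell by a small amount (-0.17 ± 0.04). Some of these calls were lost when a library was left out, which also leaves less to estimate the spread from. Without control replicate 1 the adjusted p was 0.0721 for GLUL, 0.102 for SLC1A5 and 0.219 for SLC2A1. Without control replicate 2 it was 0.103 for GLUL, 0.11 for SLC1A5 and 0.069 for SLC2A1, and without glucose deprivation replicate 2 it was 0.075 for CHAC1 and 0.161 for SLC2A1. Over all alternatives the highest adjusted p was 0.826 for GLUL, 0.146 for SLC1A5, 0.228 for SLC2A1 and 0.138 for CHAC1.

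The lists on aminoacyl-tRNA synthetases (median 0.15, 10 higher and 7 lower of 20), one-carbon metabolism (0.03, 6 higher and 6 lower of 14), autophagy and lysosome (0.09, 15 higher and 12 lower of 38), hypoxia (0.14, 9 higher and 6 lower of 19), immediate early genes (0.13, 4 higher and 3 lower of 13), extracellular matrix (0.12, 8 higher and 3 lower of 19) and abundant non-coding RNAs (0.11, 7 higher and 2 lower of 16) did not pass the camera test. Neither did those on glutamine metabolism (-0.14, 3 higher and 12 lower of 22), hexosamine synthesis (-0.03, 2 higher and 8 lower of 17), fatty acid synthesis (-0.04, 6 higher and 6 lower of 16), glucose sensing (-0.17, 3 higher and 5 lower of 10), mitochondrially encoded mRNAs (-0.17, 2 higher and 5 lower of 13), apoptosis regulators (-0.05, 5 higher and 9 lower of 22), NF-kB targets (-0.12, 1 higher and 4 lower of 8) and epithelial or mesenchymal genes (0.01, 5 higher and 3 lower of 15); the smallest of their adjusted p-values was 0.0574, for glutamine metabolism. Under scaling to the total the medians of the hexosamine, fatty acid and apoptosis lists lay above 0. Single members of these lists moved, such as the serine pathway gene MTHFD2 (0.87 ± 0.04 log2), the intermediate filament gene VIM (0.88 ± 0.06) and the proline synthesis gene PYCR3 (-1.20 ± 0.05). Of 29 markers of other cell types 1 passed the filter, SYP, at 2.26 ± 0.362 FPKM in control and 4.16 ± 0.568 FPKM without glucose.

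**Figure D1:**
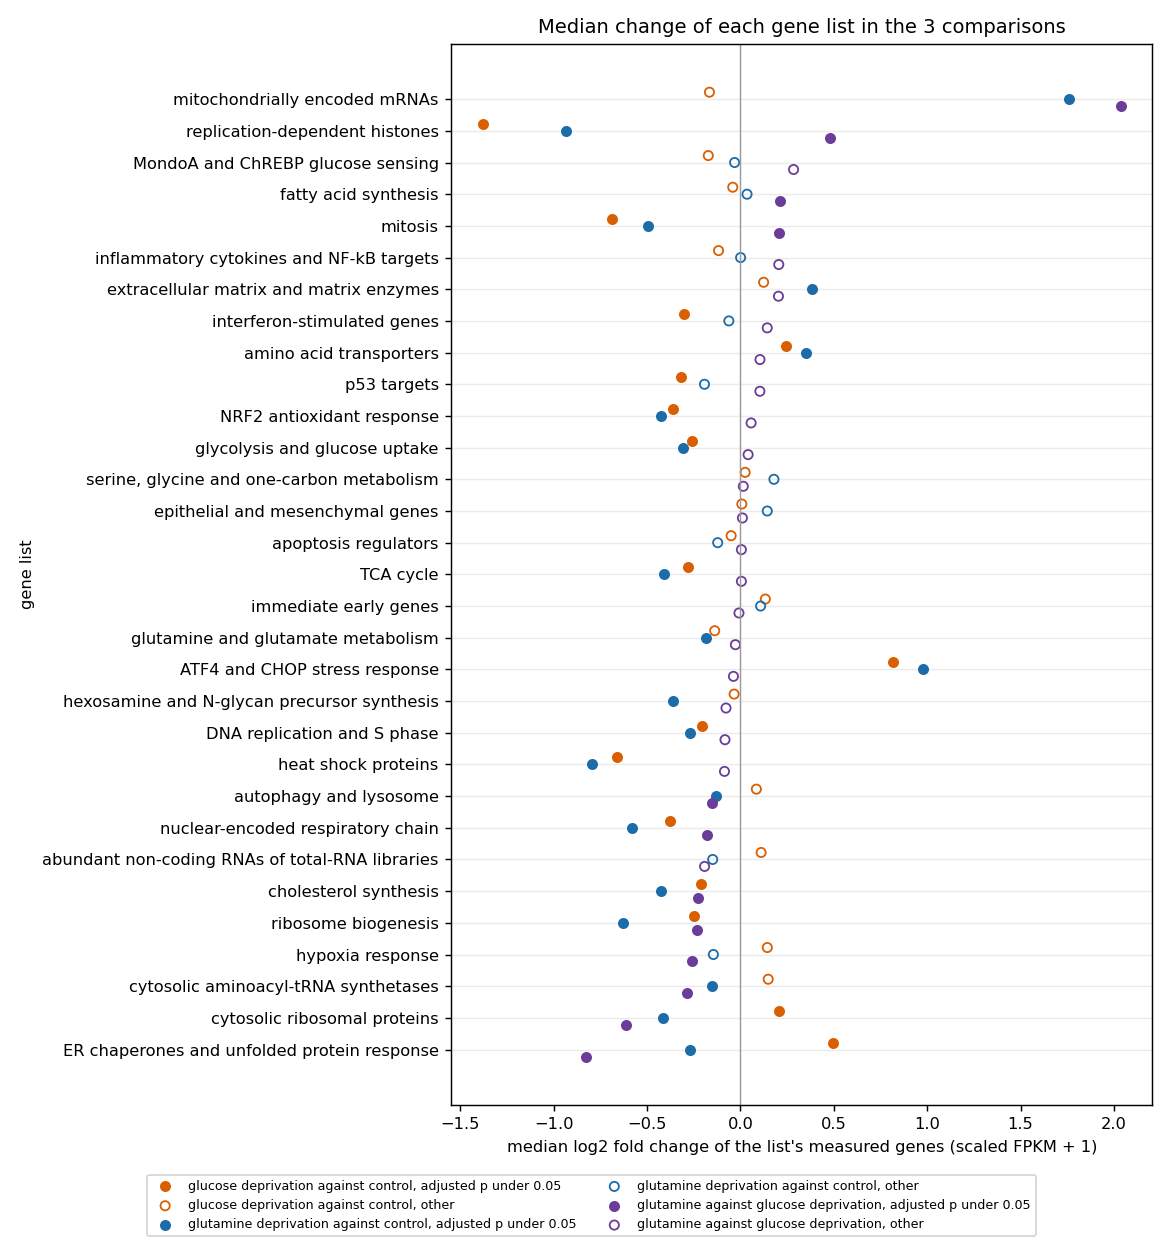
Median log2 fold change (horizontal axis, scaled FPKM + 1) of the measured genes of each gene list fixed in advance (vertical axis) in the 3 comparisons; filled points passed the camera test at an adjusted p under 0.05 with the preset correlation. ER chaperone genes lie at 0.49 in glucose deprivation and at -0.27 in glutamine deprivation (0.01 under scaling to the total), and mitochondrially encoded mRNAs at 1.76 in glutamine deprivation.

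The second comparison asked the same of glutamine removal, with 1 deprived library, which is assumed to vary like the other groups; the difference has no replicate check of its own. MT-CYB, the cytochrome b gene, went from 72.3 ± 3.21 FPKM in control to 421 FPKM (2.53 ± 0.10 log2, adjusted p = 2.21e-05) and MT-ND5, a complex I subunit, from 25.4 ± 1.86 to 150.04 FPKM (2.52 ± 0.15 log2, adjusted p = 3.44e-05). CHAC1, a glutathione-degrading enzyme gene induced by ATF4, rose from 0.926 ± 0.512 to 9.65 FPKM (2.49 ± 0.20 log2, adjusted p = 7.27e-05). The heat shock gene HSPA1B fell from 91.9 ± 2.75 to 21.7 FPKM (-2.03 ± 0.09 log2, adjusted p = 2.56e-05) and the transferrin receptor gene TFRC from 52.7 ± 0.354 to 18.6 FPKM (-1.46 ± 0.05 log2, adjusted p = 1.33e-05).

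MT-ND4 (2.39 ± 0.11 log2), MT-ND4L (2.21 ± 0.10), MT-ND1 (1.96 ± 0.14) and MT-ND2 (1.77 ± 0.09) were among the genes with the largest rises; copies of mitochondrial sequence in the nuclear genome can share their reads. The RNA polymerase II subunit gene POLR2A rose from 12.5 ± 1.44 to 46.4 FPKM and the splicing factor gene SRRM2 from 14.1 ± 1.41 to 51.2 FPKM. The histone genes H2AC18 (-2.07 ± 0.16 log2), H3C13 (-1.94 ± 0.17), H3C1 (-1.63 ± 0.07), H2AC4 (-1.47 ± 0.10) and H2AC12 (-1.40 ± 0.08) fell, with the same uncertainty over copies as above, as did CHAC2 (-1.42 ± 0.08), a relative of CHAC1. On GRCh38, CHAC1 lies on chromosome 15 from 40953471 to 40956512, TFRC on chromosome 3 from 196049284 to 196082090, POLR2A on chromosome 17 from 7484366 to 7514616, SRRM2 on chromosome 16 from 2752638 to 2771412 and SESN2 on chromosome 1 from 28259518 to 28282491.

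The test called 8476 of 16598 genes at an adjusted p under 0.05 (limma), 4087 higher and 4389 lower, of which 404 and 119 changed at least 2-fold. The count was 5624 without control replicate 1 and 5475 without control replicate 2, and the share of higher calls was 48.2% here, 67.1% on the values as deposited, 68.0% under upper-quartile scaling and 90.9% under scaling to the total. These scalings moved the median log2 fold change of all genes from 0.04 to 0.17, 0.18 and 0.29, so directions of small changes are relative to that median. In libraries simulated for this comparison 17.5% of calls were false, which does not estimate the share among the real calls.

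Fold changes in the glutamine-deprived library also followed transcript properties. Across 11675 protein-coding genes, which are not independent replicates, Spearman's rho with the GC content of the longest transcript was 0.33 and with its length 0.34, against 0.03 and 0.21 in glucose deprivation. The fifth of genes with the shortest transcripts had a median log2 fold change of -0.28 and the fifth with the longest 0.13. After removal of both trends the list calls below held, apart from those named. The 4406 genes with a mean of at least 10 FPKM had a median of -0.31 and the less abundant genes 0.16. Camera compared each list with all genes, not with genes of like abundance. Falls to medians no lower than -0.31 therefore cannot be told apart from the fall of abundant genes in general. This holds for the glycolysis, ER chaperone, S phase, glutamine metabolism, synthetase and autophagy lists.

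The ATF4 and CHOP stress response list rose, with 20 of 24 members higher and 0 lower, also when adjusted over the list alone. The median was 0.98 (camera adjusted p = 1.14e-07, or adjusted p = 0.395 with an estimated correlation). The mTORC1 inhibitor genes SESN2 (from 15.7 ± 0.227 to 49.4 FPKM) and DDIT4 (from 22.8 ± 3.46 to 57.2 FPKM) and the secreted glycoprotein gene STC2 (1.23 ± 0.06 log2) rose. DDIT3 went to 15.3 FPKM (1.38 ± 0.06 log2), ASNS to 48.4 FPKM (1.09 ± 0.06) and TRIB3 to 11.1 FPKM (0.79 ± 0.08). Amino acid transporter genes rose in 13 of 21 cases with 1 lower (13 and 2 adjusted over the list alone). The median was 0.35 (camera adjusted p = 0.00137, or adjusted p = 0.395 with an estimated correlation). It was 0.605 under scaling to the total. SLC7A1 rose from 15.0 ± 0.286 to 40.0 FPKM, SLC7A11 from 8.19 ± 0.0635 to 18.8 FPKM, the leucine transporter gene SLC7A5 by 0.72 ± 0.06 log2 and SLC1A5 by 0.55 ± 0.06 log2. Mitochondrially encoded mRNAs rose in 10 of 13 cases with 1 lower, also when adjusted over the list alone. Their median was 1.76 (camera adjusted p = 0.000716, or adjusted p = 0.487 with an estimated correlation). The lower one was MT-ND6, at 27.4 FPKM against 49.95 ± 0.979 FPKM in control, a call lost without a filter on low values (adjusted p = 0.0652). Extracellular matrix genes rose in 13 of 19 cases with 0 lower (14 higher adjusted over the list alone). The median was 0.38 (camera adjusted p = 0.000424, or adjusted p = 0.395 with an estimated correlation). The collagen VI gene COL6A1 changed by 0.66 ± 0.09 log2, a call lost without a filter on low values (adjusted p = 0.0532), and the laminin gene LAMB1 by 0.38 ± 0.05 log2.

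**Figure D2:**
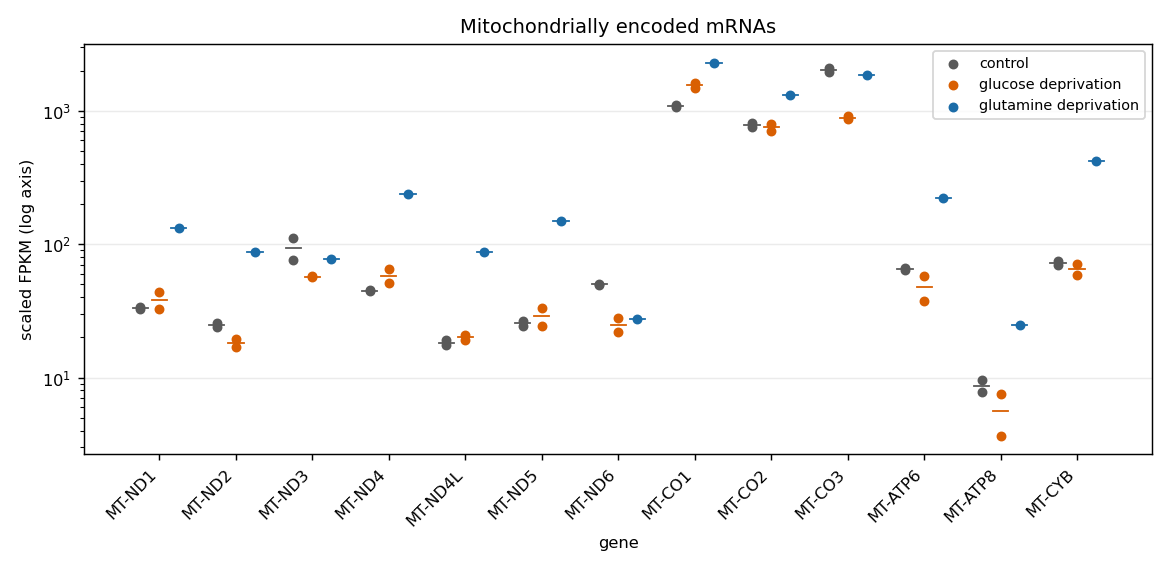
Scaled FPKM (vertical log axis) of the 13 mitochondrially encoded mRNAs (horizontal axis) in each library; points are libraries and short lines group means. MT-CYB lies at 421 FPKM in the glutamine-deprived library against 72.3 ± 3.21 (SD, n = 2) in control, whereas MT-ND6 lies at 27.4 FPKM against 49.95 ± 0.979.

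Genes of ribosomes and their assembly fell. Of 78 cytosolic ribosomal protein genes 69 were lower and 0 higher (71 lower adjusted over the list alone). The median was -0.42 (camera adjusted p = 2.12e-13, and 3.19e-11 after removal of the GC and length trends, or adjusted p = 0.456 with an estimated correlation). The median was -0.24 under upper-quartile scaling and -0.10 under scaling to the total. RPS26 fell from 126 ± 3.76 to 70.3 FPKM and RPL34 from 121 ± 3.02 to 75.5 FPKM. Ribosome biogenesis genes fell in 24 of 28 cases with 1 higher, also when adjusted over the list alone. Their median was -0.63 (camera adjusted p = 1.33e-09, or adjusted p = 0.395 with an estimated correlation). NOP16 changed by -1.26 ± 0.05 log2, RRP9 by -1.12 ± 0.06 and the nucleolar helicase gene DDX21 by -0.93 ± 0.05. Heat shock protein genes fell in 14 of 17 cases with 0 higher (15 and 1 adjusted over the list alone). The median was -0.79 (camera adjusted p = 2.6e-06, or adjusted p = 0.395 with an estimated correlation). The constitutive chaperone gene HSPA8 went from 321 ± 30.7 to 146 FPKM. In the ER chaperone list 16 of 26 members fell and 5 rose (17 and 5 adjusted over the list alone, camera adjusted p = 0.00591, adjusted p = 0.395 with an estimated correlation); the median was -0.27 and 0.01 under scaling to the total. SDF2L1 (-0.92 ± 0.09 log2), the secreted ER stress factor gene MANF (-0.85 ± 0.06) and the calreticulin gene CALR (-0.71 ± 0.05) fell.

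Cell division genes fell in this comparison too. In the mitosis list 30 of 34 members fell and 1 rose (31 and 1 adjusted over the list alone). The median was -0.50 (camera adjusted p = 3.02e-10, or adjusted p = 0.395 with an estimated correlation). The spindle checkpoint gene MAD2L1 changed by -0.90 ± 0.06 log2 and CCNB1 by -0.81 ± 0.06 log2. Replication-dependent histone genes fell in 20 of 21 cases with 0 higher, also when adjusted over the list alone. Their median was -0.94 (camera adjusted p = 1.72e-08, or adjusted p = 0.454 with an estimated correlation). H1-3 changed by -1.32 ± 0.07 log2. In the S phase list 26 of 38 members fell and 4 rose (27 and 4 adjusted over the list alone, camera adjusted p = 0.000224, adjusted p = 0.405 with an estimated correlation); the median was -0.27 and 0.03 under scaling to the total. The cyclin E2 gene CCNE2 fell (-0.84 ± 0.06 log2) and CDT1 rose (0.85 ± 0.08).

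Among metabolic lists, nuclear-encoded respiratory chain genes fell in 38 of 40 cases with 0 higher (39 lower adjusted over the list alone). The median was -0.58 (camera adjusted p = 2.16e-13, and 5.09e-14 after removal of the GC and length trends, or adjusted p = 0.405 with an estimated correlation). The complex I gene NDUFB3 changed by -1.19 ± 0.09 log2 and CYCS by -1.13 ± 0.06. Cholesterol synthesis genes fell in 18 of 24 cases with 1 higher, also when adjusted over the list alone. The median was -0.43 (camera adjusted p = 1.28e-05, or adjusted p = 0.395 with an estimated correlation). Members included the isomerase gene IDI1 (-0.95 ± 0.05 log2). TCA cycle genes fell in 16 of 25 cases with 1 higher, also when adjusted over the list alone. Their median was -0.41 (camera adjusted p = 0.000224, or adjusted p = 0.405 with an estimated correlation). PDHB changed by -0.69 ± 0.06 log2. NRF2 antioxidant genes fell in 13 of 18 cases with 3 higher, also when adjusted over the list alone. The median was -0.43 (camera adjusted p = 0.00299, or adjusted p = 0.405 with an estimated correlation). The thioredoxin gene TXN changed by -0.90 ± 0.06 log2. In the glycolysis list 12 of 22 members fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.000645, adjusted p = 0.456 with an estimated correlation); the median was -0.31 and 0.00 under scaling to the total. The monocarboxylate transporter gene SLC16A1 (-0.76 ± 0.05 log2) and LDHA (-0.58 ± 0.06) fell, while HK2 (-0.07 ± 0.08, adjusted p = 0.494) did not pass. Under scaling to the total the medians of other lists that fell lay nearer to 0. They were -0.62 for histone genes, -0.33 for ribosome biogenesis, -0.27 for the respiratory chain, -0.19 for mitosis, -0.14 for the NRF2 list, -0.13 for the TCA cycle and -0.12 for cholesterol synthesis. Single genes named above that lost their calls under that scaling were CALR (adjusted p = 0.132), LDHA (adjusted p = 0.353), PDHB (adjusted p = 0.0875), RPL34 (adjusted p = 0.174) and SLC16A1 (adjusted p = 0.084).

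Hexosamine synthesis genes fell in 11 of 17 cases with 2 higher, also when adjusted over the list alone. The median was -0.36, and -0.07 under scaling to the total (camera adjusted p = 0.0154, and 0.0625 under scaling to the total, or adjusted p = 0.456 with an estimated correlation). UAP1 changed by -0.65 ± 0.05 log2, a call lost under scaling to the total (adjusted p = 0.139). In the glutamine and glutamate metabolism list 12 of 22 members fell and 2 rose, also when adjusted over the list alone. The median was -0.18 (camera adjusted p = 0.00843, or adjusted p = 0.395 with an estimated correlation). That call was lost on the values as deposited (adjusted p = 0.0509), under upper-quartile scaling (adjusted p = 0.0542) and under scaling to the total, where the median was 0.10 (adjusted p = 0.11). Its adjusted p over the alternatives tested with camera at the preset correlation lay between 0.00764 and 0.11. GLUL went from 37.7 ± 0.511 to 22.6 FPKM, a call lost under scaling to the total (-0.41 log2, adjusted p = 0.104), and the purine synthesis gene PPAT from 35.8 ± 0.506 to 19.9 FPKM, while the alanine aminotransferase gene GPT2 rose by 0.65 ± 0.06 log2. Synthetase genes (10 of 20 lower, 3 higher, also when adjusted over the list alone) passed narrowly (camera adjusted p = 0.0459, adjusted p = 0.456 with an estimated correlation). Without control replicate 1 or 2 their call was lost. Over the alternatives tested with camera at the preset correlation, their adjusted p lay between 0.0253 and 0.285. Their median of -0.15 became 0.02 under upper-quartile scaling, 0.01 on the values as deposited and 0.16 under scaling to the total, where the call was lost too. In the autophagy and lysosome list 16 of 38 members fell and 3 rose, also when adjusted over the list alone (camera adjusted p = 0.0459, adjusted p = 0.474 with an estimated correlation). It lost its call after removal of the GC and length trends (adjusted p = 0.121), without control replicate 2 and without glucose deprivation replicate 2. The adjusted p of this list over the alternatives tested with camera at the preset correlation lay between 0.0319 and 0.252. Its median of -0.13 became 0.02 under upper-quartile scaling, 0.00 on the values as deposited and 0.14 under scaling to the total, where the call was lost too; the lysosomal galactosidase gene GLA changed by -1.15 ± 0.05 log2.

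TXNIP rose without glutamine, from 6.21 ± 0.129 to 9.81 FPKM (0.58 ± 0.08 log2, adjusted p = 0.000626), and ARRDC4 did not pass (-0.07 ± 0.08, adjusted p = 0.455). SLC2A1 fell (-0.34 ± 0.10), as did HSPA5 (-0.26 ± 0.07), which lies at 0.06 under scaling to the total. Without control replicate 1 or 2 the adjusted p was 0.156 or 0.109 for HSPA5 and 0.0584 or 0.162 for SLC2A1; over all alternatives the highest was 0.846 for HSPA5 and 0.787 for SLC2A1. Lists that did not pass had medians of 0.18 (one-carbon metabolism), -0.14 (hypoxia), 0.04 (fatty acid synthesis), -0.03 (glucose sensing), -0.19 (p53 targets), -0.12 (apoptosis regulators), -0.06 (interferon-stimulated genes), 0.11 (immediate early genes), 0.14 (epithelial and mesenchymal genes), 0.00 (NF-kB targets) and -0.15 (abundant non-coding RNAs), the smallest adjusted p being 0.0851 for hypoxia. Under scaling to the total the medians of the glucose sensing, hypoxia, p53, apoptosis, interferon and non-coding RNA lists lay above 0. After removal of the GC and length trends the one-carbon and the epithelial and mesenchymal lists passed upward, with adjusted p-values of 0.0445 and 0.0356. The fatty acid synthase gene FASN rose from 35.7 ± 0.426 to 69.8 FPKM. SYP, the only measured marker of other cell types, stood at 3.17 FPKM.

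**Figure D3:**
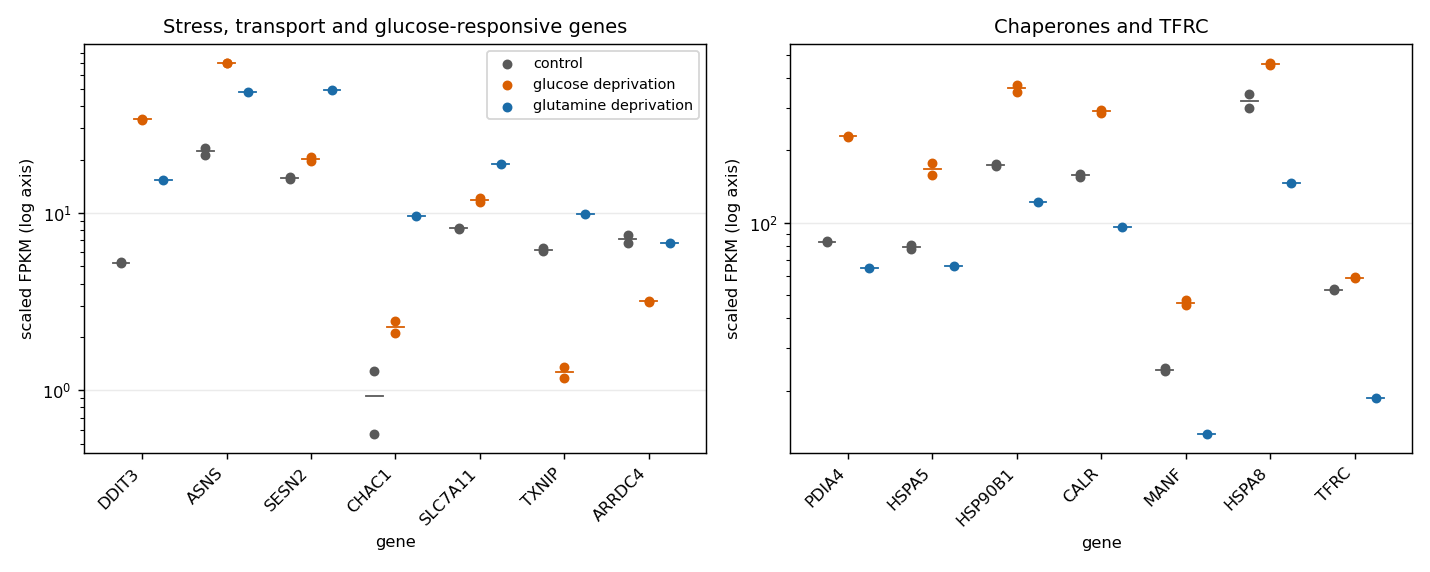
Scaled FPKM (vertical log axes) of stress, transport and glucose-responsive genes (left) and of chaperone genes and TFRC (right) in each library; points are libraries and short lines group means. TXNIP lies at 1.27 ± 0.133 FPKM (SD, n = 2) without glucose and at 9.81 FPKM without glutamine, and PDIA4 at 228 ± 0.353 and 64.5 FPKM.

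The comparisons with control overlapped. Of the genes called in each, 2159 were higher in both and 2795 lower in both, against 1083 and 1241 for independent lists of these sizes, and 813 were called in opposite directions. Together the shared calls numbered 4954, which became 2865 without control replicate 1, 2879 without control replicate 2 and 2553 under scaling to the total. The log2 fold changes correlated across genes with r = 0.58, and unchanged groups simulated against shared controls gave r = 0.41. The covariance was 0.124 against 0.0111 simulated. Those simulations gave a mean of 0 shared calls in either direction, but they hold no changed genes. An overlap with a separate control library for each deprivation was not computed, so part of the excess of shared calls may come from the shared controls. Both deprived media held dialyzed serum and the labels name none for the control, so serum may account for shared calls too, which was not tested. ASNS, DDIT3, SLC7A1 and NEAT1 were among the genes that rose in both, and CCNB1, CYCS, PRDX1 and HSPE1 among those that fell in both.

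The third comparison set glutamine against glucose deprivation directly, with dialyzed serum on both sides. The controls still entered through the estimate of the spread, the scaling and the filter on low values. TXNIP was higher without glutamine (1.27 ± 0.133 FPKM without glucose, 9.81 without glutamine; 2.26 ± 0.08 log2, adjusted p = 1.29e-05), as was MT-CYB (64.6 ± 8.56 and 421 FPKM; 2.69 ± 0.10 log2, adjusted p = 1.76e-05). PDIA4 was lower without glutamine (228 ± 0.353 and 64.5 FPKM; -1.81 ± 0.05 log2, adjusted p = 9.13e-06), and so were MANF (-1.74 ± 0.06 log2), HSPA8 (-1.64 ± 0.09), TFRC (-1.62 ± 0.05) and CALR (-1.59 ± 0.05). MT-ND5 (2.36 ± 0.15), MT-ATP6 (2.24 ± 0.20), MT-ND2 (2.20 ± 0.09) and H1-3 (2.22 ± 0.07) were higher without glutamine. Of the genes in this paragraph, TXNIP, MT-ATP6, MT-ND2, PDIA4, MANF, HSPA8, TFRC and CALR had passed in opposite directions against control. On GRCh38, MANF lies on chromosome 3 from 51385291 to 51389397, HSPA8 on chromosome 11 from 123057489 to 123062462 and CALR on chromosome 19 from 12938609 to 12944489.

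This test called 7375 of 16598 genes at an adjusted p under 0.05 (limma), 3715 higher and 3660 lower without glutamine, of which 237 and 102 differed at least 2-fold. The share of higher calls was 50.4% here, 62.3% under upper-quartile scaling, 67.9% on the values as deposited and 85.4% under scaling to the total, where the count was 4098 and the median log2 fold change of all genes 0.18, against 0.01 here. In libraries simulated for this comparison 8.38% of calls were false, which does not estimate the share among the real calls. The glutamine side rests on the same lone library. Across 11675 protein-coding genes, which are not independent replicates, fold changes correlated with the GC content of the longest transcript (Spearman's rho 0.33) and with its length (0.17). The 4406 genes with a mean of at least 10 FPKM had a median of -0.13 and the less abundant genes 0.07, and the list tests did not allow for abundance.

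ER chaperone genes were lower without glutamine in 22 of 26 cases and higher in 2 (23 and 2 adjusted over the list alone). Their median was -0.83 (camera adjusted p = 2.5e-10, or adjusted p = 0.532 with an estimated correlation). HSP90B1 changed by -1.57 ± 0.06 log2 and HSPA5 by -1.33 ± 0.07. All 78 ribosomal protein genes were lower, also when adjusted over the list alone. The median was -0.61 (camera adjusted p = 1.77e-23, or adjusted p = 0.643 with an estimated correlation). RPS12 changed by -0.93 ± 0.06 log2. Ribosome biogenesis genes were lower in 17 of 28 cases and higher in 1 (17 and 2 adjusted over the list alone). The median was -0.23 (camera adjusted p = 0.000609, or adjusted p = 0.643 with an estimated correlation). RRS1 changed by -1.28 ± 0.06 log2. Synthetase genes were lower in 13 of 20 cases and higher in 1, also when adjusted over the list alone. Their median was -0.29 (camera adjusted p = 0.0028, or adjusted p = 0.643 with an estimated correlation). SARS1 changed by -0.70 ± 0.05 log2. Cholesterol synthesis genes were lower in 14 of 24 cases and higher in 2, also when adjusted over the list alone. The median was -0.23 (camera adjusted p = 0.00436, or adjusted p = 0.643 with an estimated correlation). The squalene epoxidase gene SQLE changed by -0.996 ± 0.05 log2. Hypoxia genes were lower in 10 of 19 cases and higher in 4, also when adjusted over the list alone. The median was -0.26 (camera adjusted p = 0.0143, or adjusted p = 0.643 with an estimated correlation). P4HA1 changed by -0.60 ± 0.06 log2, a call lost under scaling to the total (adjusted p = 0.0984). Respiratory chain genes were lower in 20 of 40 cases and higher in 0 (22 lower adjusted over the list alone, camera adjusted p = 0.000286, adjusted p = 0.729 with an estimated correlation); their median was -0.18, and 0.01 under scaling to the total, where the call was lost (adjusted p = 0.0733). Autophagy and lysosome genes were lower in 14 of 38 cases and higher in 3 (15 and 3 adjusted over the list alone, camera adjusted p = 0.00317, adjusted p = 0.643 with an estimated correlation), with the sialidase gene NEU1 at -1.38 ± 0.06 log2; their median was -0.15, and 0.04 under scaling to the total, where the call was lost (adjusted p = 0.0639). That scaling moved the medians of the synthetase, hypoxia, ribosome biogenesis and cholesterol lists to -0.09, -0.08, -0.04 and -0.03.

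Mitochondrially encoded mRNAs were higher without glutamine in 11 of 13 cases and lower in 0 (12 higher adjusted over the list alone). Their median was 2.04 (camera adjusted p = 1.9e-06, or adjusted p = 0.656 with an estimated correlation). Histone genes had fallen further without glucose, and 15 of 21 were higher without glutamine and 0 lower, also when adjusted over the list alone. The median was 0.48 (camera adjusted p = 0.000176, or adjusted p = 0.704 with an estimated correlation). Mitosis genes were higher in 17 of 34 cases and lower in 4 (21 and 4 adjusted over the list alone). Their median was 0.21 (camera adjusted p = 0.000686, or adjusted p = 0.656 with an estimated correlation). It was 0.40 under scaling to the total. PLK1 changed by 0.99 ± 0.05 log2 and the proliferation marker gene MKI67 by 1.01 ± 0.09. Fatty acid synthesis genes were higher in 10 of 16 cases and lower in 2, also when adjusted over the list alone (median 0.21, camera adjusted p = 0.0253, adjusted p = 0.643 with an estimated correlation); this call was lost after removal of the GC and length trends (adjusted p = 0.108) and under scaling to the total (median 0.39, adjusted p = 0.0681).

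The ATF4 and CHOP list did not differ by the camera test (8 of 24 higher without glutamine, 7 lower, median -0.04, or 0.17 under scaling to the total, adjusted p = 0.777), and its members parted. DDIT4 (1.33 ± 0.11 log2), SESN2 (1.25 ± 0.05) and CHAC1 (1.70 ± 0.20) were higher without glutamine, DDIT3 (-1.09 ± 0.06), PPP1R15A (-0.80 ± 0.05) and ASNS (-0.53 ± 0.06) were lower, and TRIB3 (-0.20 ± 0.08, adjusted p = 0.0669) did not pass, though it did after removal of the GC and length trends (-0.27 log2, adjusted p = 0.00883) and among protein-coding genes alone (adjusted p = 0.0412). Amino acid transporter genes did not differ as a list either (median 0.10, adjusted p = 0.681), with SLC3A2 lower (-1.18 ± 0.07 log2) and SLC7A5 (0.75 ± 0.06), SLC7A11 (0.63 ± 0.05) and SLC1A5 (0.36 ± 0.06) higher. ARRDC4 (0.89 ± 0.08) was higher without glutamine, and HK2 (-0.63 ± 0.08), SLC2A1 (-0.61 ± 0.10) and GLUL (-0.55 ± 0.05) were lower. Under scaling to the total the calls of HK2 (adjusted p = 0.0658), SLC2A1 (adjusted p = 0.0533), GLUL (-0.35 log2, adjusted p = 0.207) and ASNS (-0.33 log2, adjusted p = 0.233) were lost. Without a filter on low values those of SLC2A1 (adjusted p = 0.0798), CHAC1 (adjusted p = 0.0536) and SLC1A5 (adjusted p = 0.0504) were. LDHA was higher without glutamine (0.20 ± 0.06, adjusted p = 0.0319), a call lost without control replicate 1 (adjusted p = 0.119), control replicate 2 (adjusted p = 0.122) or glucose deprivation replicate 2 (adjusted p = 0.0852), with 0.165 the highest over all alternatives. The remaining lists did not pass, with medians of 0.02 (one-carbon metabolism), -0.03 (glutamine metabolism), 0.04 (glycolysis), 0.28 (glucose sensing), -0.08 (hexosamine synthesis), 0.01 (TCA cycle), -0.08 (S phase), 0.10 (p53 targets), 0.01 (apoptosis regulators), 0.06 (NRF2 response), 0.21 (NF-kB targets), 0.14 (interferon-stimulated genes), -0.01 (immediate early genes), 0.01 (epithelial and mesenchymal genes), 0.20 (extracellular matrix), -0.09 (heat shock proteins) and -0.19 (abundant non-coding RNAs); the smallest of their adjusted p-values was 0.0569, for extracellular matrix. Under scaling to the total the medians of the glutamine metabolism, hexosamine, S phase, immediate early and heat shock lists lay above 0.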

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

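All tests of technical explanations in this part were chosen after the result was seen. The direct comparison of the deprivations singled out results that moved in opposite directions against control, and all rest on 1 glutamine-deprived library. ER chaperone genes differed by a median of -0.83 log2 (-0.826) and cytosolic ribosomal protein genes by a median of -0.61 (-0.611), both lower without glutamine. For the ER chaperone list the size of the fall in glutamine deprivation depends on the scaling. Its median was -0.27, -0.27 under RLE scaling, -0.11 under upper-quartile scaling and -0.12 on the values as deposited. Only under scaling to the total did it lie above 0, at 0.01, where the median of all genes was 0.29. The fall to -0.27 also cannot be told apart from that of abundant genes in general, whose median without glutamine was -0.31. PDIA4 differed by -1.81 ± 0.05 log2, MANF by -1.74 ± 0.06 and HSPA8 by -1.64 ± 0.09. MT-ATP6 differed by 2.24 ± 0.20 log2 and MT-ND2 by 2.20 ± 0.09, both higher without glutamine.

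Of the 13 mitochondrial mRNAs 10 rose in the glutamine-deprived library, MT-CYB by 2.53 ± 0.10 log2, while MT-ND6 fell. MT-ND6 also fell without glucose (-0.99 ± 0.10), and it did not pass in the direct comparison (0.15 ± 0.13, adjusted p = 0.377), except as higher without glucose deprivation replicate 1 (0.32, adjusted p = 0.0293). DNA carried over into the library would add about as many FPKM to each of the 13, so at most the whole level of MT-ND6, 27.4 FPKM. As 9 of the 13 rose by more, MT-CYB by 349 FPKM, DNA is argued against as the whole cause. Scaling does not account for the rise either, as the lowest median under 4 other scalings was 1.76 log2. What stays open is a property of the single library, since only 1 glutamine-deprived library was mapped. A further value column of the deposited glutamine table has the name of a glucose library as its header and was not used, so no replicate was examined for the rise. A property of the single library cannot be told apart from an effect of glutamine removal, which may also account for it.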

How the results depend on the processing

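Scaling to the total, the pseudocount of 0.1, the robust variance trend over FPKM and the removal of a GC and length trend were chosen after seeing the data; the other alternatives were planned. In the order glucose deprivation, glutamine deprivation, direct comparison and shared calls, the counts of genes were 9090, 8476, 7375 and 4954. At least 2-fold changes numbered 426, 523, 339 and 147, which follows from the stricter threshold. At an adjusted p under 0.01 the direct comparison gave 4781 genes and the shared calls 3250. Without a filter on low values the shared calls were 3169. Scaling to the total gave 5419 genes in glucose deprivation, 4098 in the direct comparison and 2553 shared calls. The 5 most abundant genes held 46.3% to 52.1% of these totals, which were 493130 and 565290 in the glucose deprivation replicates. Whether this accounts for the lower counts was not tested. Leaving out each library gave 5689 to 9099 genes in glucose deprivation, 5475 to 8418 in glutamine deprivation, 5349 to 6195 in the direct comparison and 2865 to 4492 shared calls. The shared calls were 2865 without control replicate 1 and 2879 without control replicate 2. Where a group is left with 1 library, that library is assumed to vary like the others, and without the glutamine-deprived library its comparisons have no value. Other alternatives stayed within 1.5 times the main counts.

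Of the lists, 16, 20 and 12 were called. With an estimated correlation 0, 0 and 0 were called, with a lowest adjusted p of 0.42, 0.395 and 0.532. On 2 residual degrees of freedom that version has little power, so it cannot decide whether the calls hold. The fry test, which asks whether the genes of a list move one way on balance, called 25 in glucose deprivation. Ribosomal protein genes, called there by camera, were not among them (fry adjusted p = 0.0617). In the direct comparison fry did not call the respiratory chain and histone lists, which camera had called. Leaving out each library gave 14 to 16, 18 to 20 and 12 to 12 lists.

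Over 402 combinations of a named gene and a comparison, the alternatives gave 7740 values. Of these, 7156 kept their call or lack of call, 577 of the same direction were no longer called, 5 were newly called and 2 were reversed. Values called in neither the main nor the other setting count as kept whatever their direction. Alternatives that change only thresholds, filters or the variance leave fold changes as they are, so they cannot show a reversal. Of those no longer called, 280 missed a change of at least 2-fold and 113 came from scaling to the total. The reversed values were those of HLA-C (0.000881 log2) and HSPA5 (0.0604) in glutamine deprivation under scaling to the total, which raises the median of all genes in that comparison to 0.29.

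A fit with the replicate number as a replicate block called 8805, 7552 and 6351 genes, 4469 shared, and 16, 18 and 12 lists. It ended the calls of the synthetase list and of the autophagy and lysosome list in glutamine deprivation (adjusted p = 0.0595 for each). Of the 402 combinations of a named gene and a comparison it ended 3 calls, among them LDHA in the direct comparison (0.17 log2, adjusted p = 0.142) and SOD2 in glutamine deprivation (-0.30, adjusted p = 0.0576). Deviations of control replicate 1 and glucose deprivation replicate 1 from their group means correlated across genes with r = -0.02. This shows no large deviation shared by replicates of the same number, but it cannot tell whether they were grown or prepared together. The planned count tests (edgeR with its scalings, DESeq2, limma voom) were not run, as the values are not counts. Depth limits low genes most: at 1 FPKM counting error alone is 10.1% to 12.02% for a gene of 2 kb.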

Other observations

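The GC, length and filter tests in this part were written before their results were seen, and the other tests after. The fixed list of abundant non-coding RNAs passed in neither deprivation (adjusted p = 0.113 without glucose and 0.889 without glutamine), and the genes below are single ones. The nuclear RNAs NEAT1 (1.65 ± 0.10 log2 without glucose, 1.99 ± 0.13 without glutamine) and MALAT1 (1.40 ± 0.09 and 0.78 ± 0.11, the latter call lost without a filter on low values, adjusted p = 0.0602) rose in both, as did the mitochondrial ribosomal RNAs MT-RNR1 (1.01 ± 0.05 and 2.38 ± 0.07) and MT-RNR2 (1.34 ± 0.08 and 2.77 ± 0.09), whose level also depends on how ribosomal RNA was removed. GAS5, which hosts small nucleolar RNAs and was singled out with MALAT1 after the values were seen, rose without glucose (0.95 ± 0.05) and fell without glutamine (-0.40 ± 0.06), a call lost after removal of a GC and length trend (adjusted p = 0.168) and under scaling to the total (adjusted p = 0.775). Counts of calls by class were not tested as such. Of 35 small nuclear RNAs 25 fell and 0 rose without glucose (median -1.50 log2), and 14 fell and 1 rose without glutamine (-0.48); in the direct comparison 20 were higher and 0 lower without glutamine (0.86). Of 189 small nucleolar RNAs 20 rose and 15 fell without glucose, and 2 rose and 33 fell without glutamine. Near-identical copies make each of these calls uncertain. Protein-coding genes, the largest class, had more genes lower: 3156 higher and 4399 lower of 11884 without glucose and 2896 and 4155 without glutamine. Long non-coding RNAs, pseudogenes and microRNA genes had more genes higher in both deprivations. The counts were 574 higher and 137 lower of 1935 long non-coding RNAs without glucose and 563 and 82 without glutamine, 445 and 60 of 1601 pseudogenes and then 419 and 60, and 73 and 10 of 493 microRNA genes and then 70 and 10. Genes of low abundance as a whole lay higher too, and whether these classes went beyond that was not tested.

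SLCO4A1-AS1 was chosen after its values were seen. This antisense transcript, on chromosome 20 from 62663027 to 62666621, was at 0.0383 and 0 FPKM in the controls, 145 and 137 FPKM without glucose and 114 FPKM without glutamine (7.12 ± 0.05 and 6.82 ± 0.06 log2). The sense gene SLCO4A1 fell by 0.423 log2 without glucose (-0.423), a call lost without a filter on low values (adjusted p = 0.058) and under scaling to the total (adjusted p = 0.0508), and did not pass without glutamine (0.08 ± 0.09, adjusted p = 0.467, at 5.16 FPKM). As counted, SLCO4A1 was called higher in neither deprivation, and its 5.16 FPKM without glutamine lay far below the 114 FPKM of the antisense gene. Whether further reads of the sense strand were counted to the antisense gene stays open. The strand used in counting is not given, and sense reads lost to it would lower SLCO4A1 too. A gain of silent genes to such levels is argued against by 0 other genes going from under 1 FPKM in both controls to at least 5 FPKM in all 3 deprived libraries. This does not speak to a broad gain at low levels: 13804 and 13780 genes reached 1 FPKM as deposited, before scaling, in the controls, 14772 and 14522 without glucose and 15877 without glutamine. Both deprived media held dialyzed serum and the labels name none for the control, so serum and nutrient loss may each account for it, and neither was tested.

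Genes of low abundance were higher relative to abundant ones in the glutamine-deprived library and, by less, without glucose. The medians of 12192 genes with a mean under 10 FPKM and of 4406 more abundant genes differed by 0.47 log2 without glutamine and by 0.25 without glucose. Genes at 1 FPKM in any library were tested, so a rise in the glutamine-deprived library itself brings low genes into this set. Among 9664 low and 4377 abundant genes chosen by the glucose-deprived libraries alone the gap without glutamine was 0.413, which argues against the filter as the whole cause. Genomic DNA would raise silent genes too, and the mean of 406 olfactory receptor genes rose by 0.00347 FPKM against a median rise of 0.360 FPKM of low genes, or 0.298 FPKM of those chosen by the glucose-deprived libraries. After removal of a trend over GC or over length the gap was 0.441 or 0.41, from 0.465 for genes with a known transcript, which argues against each as the whole cause. A shift of RNA content in both deprivations or the dialyzed serum may account for it, and a property of the lone library for the larger gap there, and none of these was tested.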
